A study of Homo sapiens with 16 samples.

How the data were processed

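The series holds messenger RNA sequencing of primary human lung fibroblasts, the cells that make and remodel the extracellular matrix of the lung. Per the labels, 4 libraries came from cells labelled Control, 4 from cells labelled Ad-TGFβ1 and 8 from cells labelled Ad-TGFβ1+SR8278. TGF-β1 is a growth factor that turns fibroblasts into contractile, collagen-producing myofibroblasts, and the labels do not spell out the prefix Ad. They do not say whether Control cells received a vector or a vehicle, so the differences from Control cannot be put down to TGF-β1 alone. SR8278 is a synthetic antagonist of the REV-ERB nuclear receptors, which are encoded by NR1D1 and NR1D2 and repress clock genes such as ARNTL (BMAL1). The series title names another compound, STL1267, a REV-ERB agonist, that no library label carries, so the treated libraries are called here by the label they have. Doses and times are not given in the sources used here.

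The titles number the libraries. Control libraries carry the numbers 1, 2, 4 and 6, and Ad-TGFβ1 libraries the numbers 7, 8, 10 and 12. Those labelled Ad-TGFβ1+SR8278 carry the numbers 19, 20, 22 and 24 and the numbers 25, 28, 29 and 30. Read in blocks of 6 numbers, each of the other labels fills 1 block, while Ad-TGFβ1+SR8278 fills 19 to 24 and 25 to 30. A comparison of these runs of title numbers was set as a check of homogeneity before the data were examined, and neither run was given a condition of its own. Replicate numbers in the text follow accession order and pair no libraries. The labels name no donor, culture or batch, so the p-values measure the spread between these libraries, which may be technical.

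Per the series' design text, poly(A) RNA was captured on oligo-dT beads, made into strand-selected libraries and sequenced in paired-end mode. The authors deposited 1 table of expected counts, that is estimated counts per gene symbol, for 28191 symbols in 16 libraries. Of its values, 33.05% were not whole, and they were rounded to whole numbers here before testing. Per the submitters' processing notes, the genome build hg38 and the program edgeR were used, with no role or version stated. The aligner, the program that estimated the counts, the gene annotation and whether the counting used strand are not given in the sources used here. Estimated counts can move reads between paralogs, pseudogenes and overlapping genes. Values of ACTA2 and ACTG2, of CXCL2 and its close paralogs, of histone genes and of the antisense gene PAPPA-AS1 are therefore less certain than the others.

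The total count per library ran from 15.9 to 27.1 M counts. Floors and errors cover no more than counting and spread between libraries, since PCR copies were not marked by molecular identifiers. A count of 0 in a group was treated as at most 3 counts summed over the group's libraries. Normalised values are CPM (counts per 1e6) of the library total times its TMM (trimmed mean of M-values) factor over all 16 libraries. Replicate libraries were compared before averaging. The chi-square per gene between libraries of a group ran from 3.50 to 209.8, so none agreed within sampling noise, and the median Pearson r across genes was 0.986. It ran from 3.50 to 22.4 within Control and Ad-TGFβ1. Within Ad-TGFβ1+SR8278 it ran from 4.64 to 92.1 among title numbers 24 and below, from 8.45 to 101 among 25 and above, and from 118 to 209.8 between the runs. The pattern of sex-linked genes differed from the majority in 0 libraries.

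Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM scaling and the filterByExpr filter, in a separate fit for each comparison that held only its own libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 are called. The standard error of a log2 fold change is its size divided by the square root of F. It is approximate and can understate the counting error of a gene with few counts in a group. Comparisons were Ad-TGFβ1 against Control, Ad-TGFβ1+SR8278 against Ad-TGFβ1, Ad-TGFβ1+SR8278 against Control, and title numbers 25 and above against 24 and below within the label Ad-TGFβ1+SR8278. Measures of whole libraries were compared by exact two-sided permutation tests, adjusted over 20 tests.

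Before the data were examined, 27 gene lists were fixed, which hold 612 genes, 598 of them in the table. They cover the contractile cytoskeleton, collagens, matrix glycoproteins, proteoglycans and hyaluronan, collagen processing and crosslinking, matrix proteases and their inhibitors, early TGF-β/SMAD response, BMP and ID targets, the circadian clock, interferon response, inflammatory NF-κB targets, the cell cycle, cholesterol synthesis, fatty acid and lipid storage, the ATF4 amino acid response, endoplasmic reticulum (ER) stress, hypoxia and glycolysis, NRF2 targets, p53 targets, YAP and WNT targets, AhR (aryl hydrocarbon receptor) and xenobiotic targets, and quiescent alveolar fibroblast genes. The others hold markers of epithelial, endothelial, immune, smooth muscle or pericyte, and mesothelial cells. Each list was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists with at least 3 tested members. The camera test with an estimated correlation and fry were alternatives.

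The rule for the genes named in the text was also fixed before the data were examined. It takes TGFB1, ACTA2, COL1A1, FN1, NR1D1, NR1D2 and ARNTL whatever their values. It adds, per comparison, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 called members of each called list by size of change, and the most abundant member of each list. The text names part of these and follows genes named in 1 comparison through the others. Genes outside the rule are said to be so. Coordinates are from GENCODE v29 on GRCh38, the assembly also called hg38.

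The tests were run first on simulated counts drawn from the means and library sizes of each comparison. Each comparison was drawn once, genes independently and with 1 spread per gene over its libraries. The shares below therefore do not allow for the runs of title numbers pooled in Ad-TGFβ1+SR8278, or for genes that vary together. The edgeR test recovered 89.4% of the 2-fold changes in Ad-TGFβ1 against Control, 57.8% in Ad-TGFβ1+SR8278 against Ad-TGFβ1, 64.6% in Ad-TGFβ1+SR8278 against Control and 71.0% between the title runs. Of its calls there, 5.85%, 2.63%, 4.50% and 2.46% were false. For DESeq2 these shares were 6.74%, 15.4%, 20.5% and 19.3%, and for voom 4.19%, 4.42%, 4.72% and 1.69%, so calls gained with DESeq2 alone are less certain. Alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter or a stricter filter on low counts, 1 fit of all 16 libraries, mitochondrially encoded genes removed, each library left out in turn, and either run of title numbers alone. Library totals without TMM and removal of the TGFB1 gene were added after seeing the data. Figures were drawn with matplotlib 3.10.9. X-linked XIST and Y-linked genes were not named or plotted.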

Results

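The data set held RNA sequencing of primary human lung fibroblasts in 16 libraries, of which 4 were labelled Control, 4 Ad-TGFβ1 and 8 Ad-TGFβ1+SR8278. The total count was 19.8 ± 2.82 M counts in Control (SD, n = 4), 25.2 ± 2.62 M counts in Ad-TGFβ1 (SD, n = 4) and 21.3 ± 2.71 M counts in Ad-TGFβ1+SR8278 (SD, n = 8). Errors of levels are standard deviations and errors of log2 fold changes are standard errors. The share of a library's counts in its 10 most abundant genes was 8.46% ± 0.564 in Control, 29.3% ± 0.625 in Ad-TGFβ1 and 20.8% ± 1.74 in Ad-TGFβ1+SR8278. The mean TMM factor was 1.30 in Control, 0.873 in Ad-TGFβ1 and 0.943 in Ad-TGFβ1+SR8278. Without TMM, a scaling added after seeing the data, the median log2 fold change of all tested genes became -0.61 for Ad-TGFβ1 against Control, 0.15 for Ad-TGFβ1+SR8278 against Ad-TGFβ1 and -0.44 for Ad-TGFβ1+SR8278 against Control. It became -0.15 and 0.13 in the first pair of these with DESeq2. Changes below are relative to the TMM scale.

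**Figure D1:**
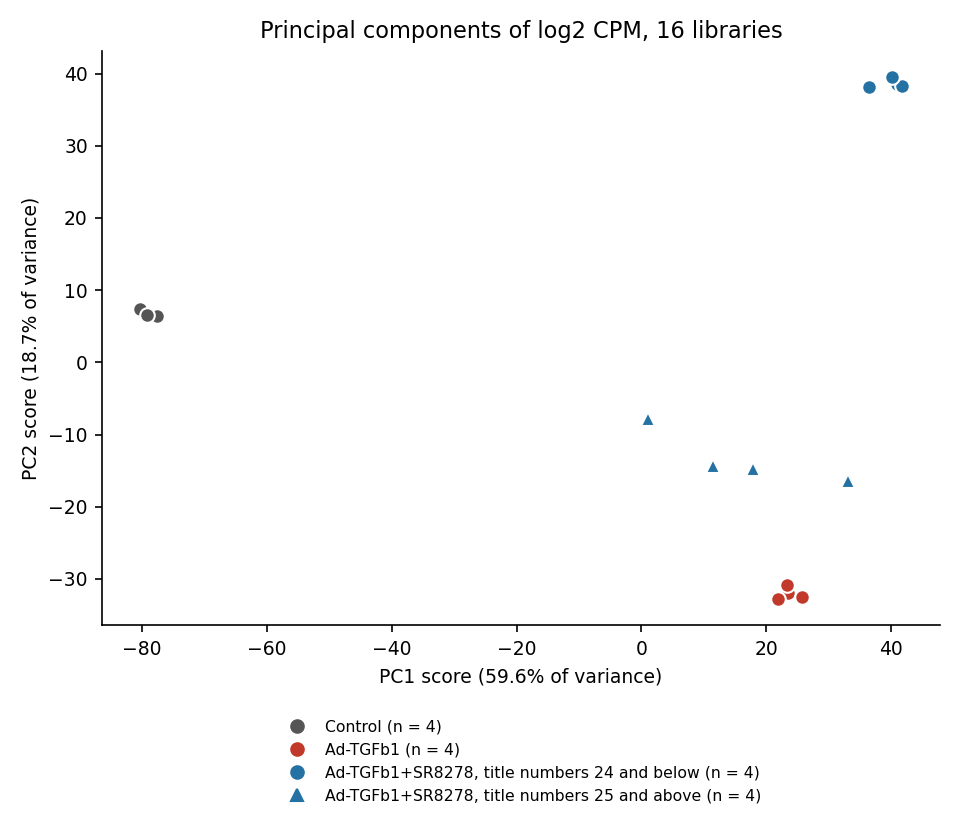
Principal components of log2 CPM in the 16 libraries, each point a library, with component 1 (59.6% of the variance) on the x axis and component 2 (18.7%) on the y axis. On component 2 the libraries labelled Ad-TGFβ1+SR8278 lay at 38.1 to 39.5 for title numbers 24 and below and at -16.5 to -7.91 for title numbers 25 and above.

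The comparison of Ad-TGFβ1 with Control asks what differed in the fibroblasts labelled Ad-TGFβ1. The TGFB1 transcript itself went from 174 ± 14.1 CPM in Control (n = 4) to 93639 ± 9652 CPM in Ad-TGFβ1 (n = 4). Counts per gene symbol cannot tell transcripts of the cells' own TGFB1 gene from any TGFB1 sequence supplied to them. ACTA2, the smooth muscle actin that marks myofibroblasts, rose from 85.3 ± 6.45 to 2035 ± 109 CPM. COL1A1, the main chain of type I collagen, rose from 3429.9 ± 764 to 71845 ± 3048 CPM, and FN1, fibronectin, from 9639.6 ± 1474 to 70637 ± 1624 CPM. Their log2 fold changes were 9.08 ± 0.12 for TGFB1, 4.58 ± 0.07 for ACTA2, 4.39 ± 0.14 for COL1A1 and 2.88 ± 0.10 for FN1. In each of these genes all 4 Ad-TGFβ1 libraries lay above all 4 Control libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.3e-15, 5.43e-15, 3.2e-12 and 4.86e-12). ARNTL, the clock activator BMAL1, fell by 0.72 ± 0.11 on the log2 scale in all 4 libraries (edgeR, Benjamini-Hochberg adjusted p = 3.51e-05), from 12.6 ± 1.99 to 7.60 ± 0.460 CPM. NR1D1, which encodes REV-ERBα, rose by 0.57 ± 0.09 in all 4 libraries (edgeR, Benjamini-Hochberg adjusted p = 5.19e-05), but its change was -0.012 (adjusted p = 0.909) without TMM, and its call was lost in 1 fit of all 16 libraries (0.57, adjusted p = 0.547). NR1D2, which encodes REV-ERBβ, had a log2 fold change of -0.10 ± 0.05 with 4 of 4 libraries below the Control mean (edgeR, Benjamini-Hochberg adjusted p = 0.0644). It passed the test without Control replicate 2 (-0.13, adjusted p = 0.0287), without TMM (-0.68, adjusted p = 1.22e-08) and with the stricter low-count filter (-0.13, adjusted p = 0.0245).

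On GRCh38 with the GENCODE v29 annotation, these are protein-coding genes. TGFB1 lies on chromosome 19 from 41301587 to 41353911, ACTA2 on chromosome 10 from 88935074 to 88991339, COL1A1 on chromosome 17 from 50183289 to 50201632 and FN1 on chromosome 2 from 215360440 to 215436172. NR1D1 lies on chromosome 17 from 40092787 to 40100725, NR1D2 on chromosome 3 from 23945260 to 23980618 and ARNTL on chromosome 11 from 13276652 to 13387266. The values count whole genes, introns and exons not being told apart.

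**Figure D2:**
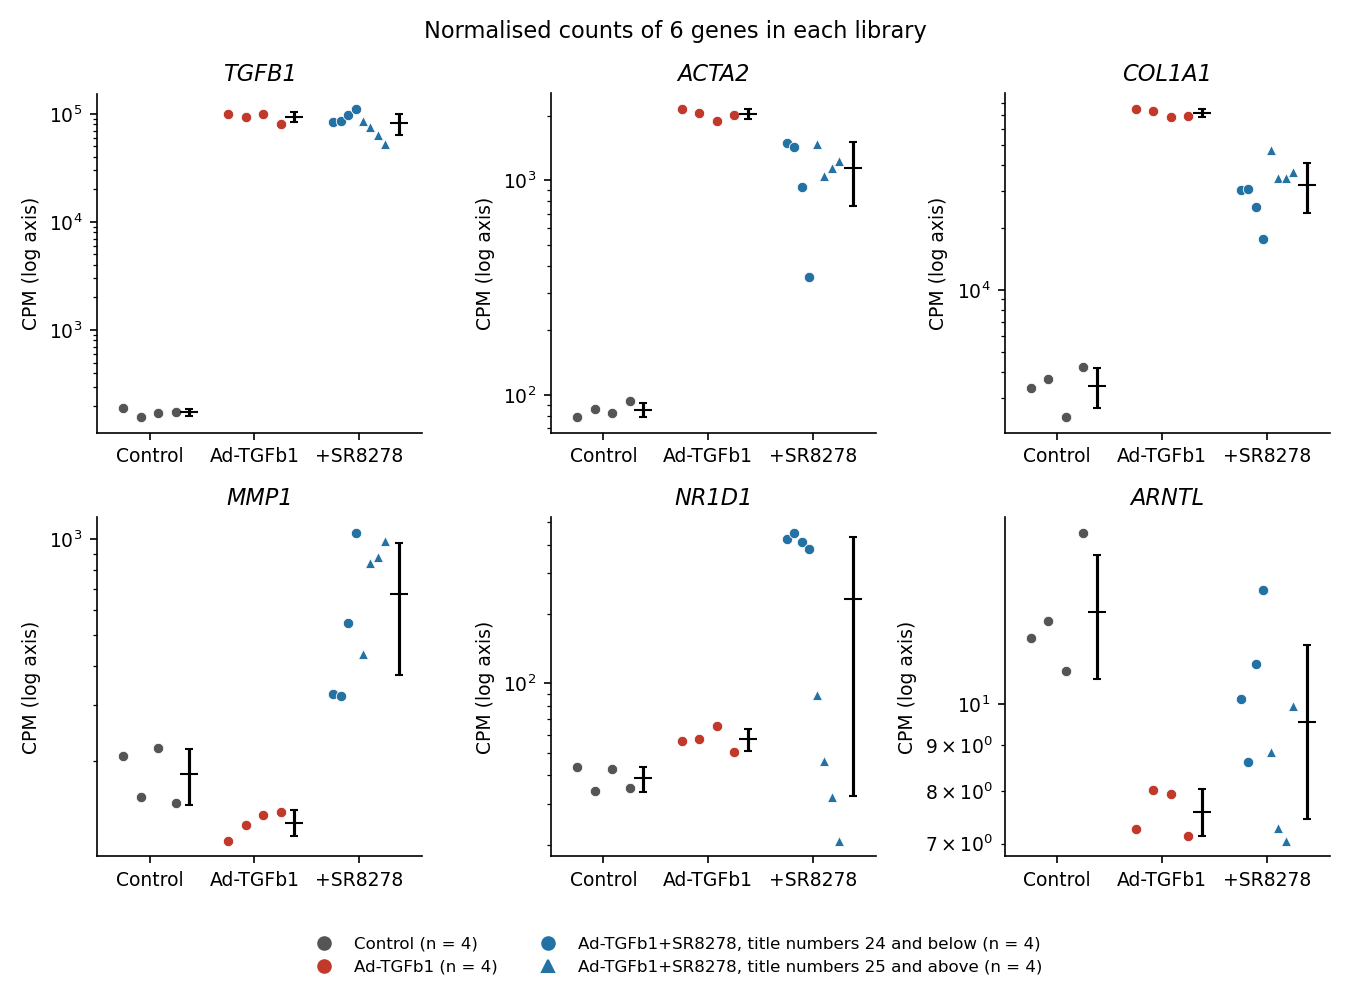
Normalised CPM (log axis) of TGFB1, ACTA2, COL1A1, MMP1, NR1D1 and ARNTL in each library by label, with crosses for the mean and bars for the SD, circles for title numbers 24 and below and triangles for 25 and above. NR1D1 averaged 416 CPM at title numbers 24 and below and 46.9 CPM at 25 and above within the label Ad-TGFβ1+SR8278, against 57.4 CPM in Ad-TGFβ1.

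Of 15060 genes tested, 5744 were higher and 5886 lower in Ad-TGFβ1 than in Control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 1890 and 2656 of them by at least 2-fold. Without TMM the split became 2528 higher and 9910 lower. Among the called genes, the libraries of the groups did not overlap in 5357 higher and 5388 lower ones. Chance gives no overlap in 2.86% of all genes, called or not, which is a different measure. Among the largest increases were KANK4, CACNA1H, MDFI, ELN, ASPN and PRG4. KANK4, a regulator of the actin cytoskeleton on chromosome 1 from 62236979 to 62319414, and CACNA1H, a T-type calcium channel on chromosome 16 from 1153121 to 1221772, had no count in the Control libraries and were at least 845-fold and at least 547-fold higher, against a floor of 3 counts over the group. MDFI, an inhibitor of myogenic transcription factors, rose by 8.32 on the log2 scale and ELN (elastin, chromosome 7 from 74027789 to 74069907) by 7.85 ± 0.18. ASPN (asporin) rose by 7.80 and PRG4 (lubricin) by 6.69. MDFI, ASPN and PRG4 had only 0.136, 0.380 and 0.498 CPM in Control, so the size of their rise is uncertain. KLHL41, a muscle kelch protein, rose by 6.62, and IGF1, insulin-like growth factor 1, by 5.44. The antisense RNA gene PAPPA-AS1 (chromosome 9 from 116398157 to 116400606) had 33.4 CPM in Control and no count in Ad-TGFβ1, at least 980-fold lower against that floor. The floor does not cover how estimated counts were shared between overlapping genes, so this bound is uncertain. Other large decreases were in the chemokine gene CCL7 at -6.46, with only 0.246 CPM left in Ad-TGFβ1, and the TNF family gene TNFSF15 at -6.35. The retinaldehyde dehydrogenase gene ALDH1A3 was at -5.99 and the alcohol dehydrogenase gene ADH1B at -5.90 ± 0.11.

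In the contractile list 15 of 21 tested genes rose and 4 fell, with ACTG2 (smooth muscle γ-actin) at 5.89, CNN1 (calponin) at 5.28 ± 0.08 and TAGLN (transgelin) at 4.41 ± 0.23 (camera adjusted p = 1.64e-07, and adjusted p = 0.211 with an estimated correlation). Of 21 collagens 19 rose and 2 fell, with a median of 2.08 and with COL11A1 at 5.54 ± 0.14, COL5A1 at 3.61 and COL15A1 at 3.16 (camera adjusted p = 4.6e-16, and adjusted p = 0.0308 with an estimated correlation). Of 26 matrix glycoproteins 17 rose and 3 fell, with COMP (cartilage oligomeric matrix protein) at 5.81 ± 0.31, SPARC (osteonectin) at 4.27 and IGFBP3 at 3.54 (camera adjusted p = 5.43e-05, and adjusted p = 0.143 with an estimated correlation). Genes of collagen processing and crosslinking rose in 18 of 23 and fell in 2, with SERPINH1, the collagen chaperone HSP47, at 3.23 and the prolyl hydroxylase gene P4HA2 at 3.21 (camera adjusted p = 7.69e-16, and adjusted p = 0.054 with an estimated correlation). Smooth muscle and pericyte markers rose in 8 of 11 and fell in 3, with NOTCH3 at 3.36 and DES (desmin) at 3.26 (camera adjusted p = 5.62e-05, and adjusted p = 0.207 with an estimated correlation). In that list 2 genes are also in the contractile list. Matrix proteases and inhibitors were called higher (camera adjusted p = 0.0281, and adjusted p = 0.113 with an estimated correlation), with 8 genes higher and 7 lower. Their median of 0.09 became -0.49 without TMM, and the call was lost without Control replicate 3 (adjusted p = 0.0630). MMP11 (stromelysin-3) rose by 5.06 ± 0.09 and ADAM19 by 4.97 ± 0.06, while PLAT, the tissue plasminogen activator, fell by 3.88 ± 0.16. In the proteoglycan list 9 of 16 genes were higher, among them BGN (biglycan) at 3.05, and 6 lower, with no call (camera adjusted p = 0.108) and a median of 0.43 that became -0.15 without TMM. Counts adjusted over the list alone equalled those given in each list of this comparison except hypoxia genes and endothelial markers.

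The ER stress, ATF4 and cholesterol lists were called higher too. All 20 tested ER stress genes rose, with a median of 1.63, among them MANF at 3.09 and HSPA5, the ER chaperone BiP, at 3.01 ± 0.07 (camera adjusted p = 4.72e-20, and adjusted p = 0.0356 with an estimated correlation). In the ATF4 amino acid list 22 of 25 rose and 2 fell, with PYCR1 of proline synthesis at 4.28 and PSAT1 of serine synthesis at 2.72 (camera adjusted p = 1.35e-10, and adjusted p = 0.0308 with an estimated correlation). Cholesterol synthesis genes rose in 19 of 24 and fell in 3, with MSMO1 at 2.21 and HMGCS1 at 1.72 (camera adjusted p = 5.72e-06, and adjusted p = 0.251 with an estimated correlation).

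Inflammatory, interferon, BMP, quiescence and cell cycle lists were called lower in Ad-TGFβ1. Of 30 inflammatory NF-κB targets 28 fell and 2 rose, with a median of -2.33, the adhesion molecule VCAM1 at -5.43 ± 0.27 and the chemokine CXCL2 at -3.58 (camera adjusted p = 5.07e-16, and adjusted p = 0.0308 with an estimated correlation). Of 39 interferon-response genes 28 fell and 3 rose, with HERC6 at -3.58 and OAS2, an antiviral synthetase, at -2.24 (camera adjusted p = 2.24e-06, and adjusted p = 0.207 with an estimated correlation). BMP and ID targets fell in 11 of 15 and rose in 3, with ATOH8 at -3.84 and BMP4 at -3.01 (camera adjusted p = 8.17e-06, and adjusted p = 0.0308 with an estimated correlation). Of 24 quiescent alveolar fibroblast genes 19 fell and 3 rose, IGF1 among the latter, with the lung mesenchyme transcription factor TCF21 at -2.97 ± 0.07 (camera adjusted p = 5.43e-05, and adjusted p = 0.056 with an estimated correlation). Cell cycle genes fell in 25 of 36 and rose in 7, with CDC20 at -3.76 and MKI67, the Ki-67 antigen, at -2.94 ± 0.12 (camera adjusted p = 0.0038, and adjusted p = 0.113 with an estimated correlation). Early TGF-β/SMAD response genes went both ways, with 12 of 30 higher and 16 lower (camera adjusted p = 0.994), a median of -0.68 and a mean of 0.29. Clock genes were higher in 10 of 21 and lower in 6 (camera adjusted p = 0.405), with a median of 0.17 that became -0.41 without TMM.

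The comparison of Ad-TGFβ1+SR8278 with Ad-TGFβ1 asks what differed with the further label SR8278. COL1A1, ELN, ACTA2 and FN1 were lower in all 8 libraries than in any of the 4 Ad-TGFβ1 libraries. COL1A1 fell by 1.17 ± 0.19 on the log2 scale, from 71845 to 32309 ± 8768 CPM (n = 8), with -1.50 ± 0.17 at title numbers 24 and below and -0.91 ± 0.10 at 25 and above (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0017, 8.45e-06 and 6.66e-04). ELN fell by 2.31 ± 0.40, from 2854 ± 89.2 to 583 ± 349 CPM, with -2.15 ± 0.34 and -2.50 ± 0.42 within the runs (edgeR, Benjamini-Hochberg adjusted p = 0.00225, 1.65e-04 and 0.00487). ACTA2 fell by 0.86 ± 0.27, to 1139 ± 379 CPM, in 8 of 8 libraries, with -0.98 ± 0.32 and -0.74 ± 0.10 within the runs (edgeR, Benjamini-Hochberg adjusted p = 0.0348, 0.0189 and 0.00146). Its pooled call was lost without Ad-TGFβ1 replicate 1, 2, 3 or 4 (adjusted p = 0.0885, 0.0829, 0.0727 and 0.0766), without Ad-TGFβ1+SR8278 replicate 3 (adjusted p = 0.0586) and without TMM (-0.74, adjusted p = 0.0525). FN1 fell by 0.92 ± 0.27 in 8 of 8 libraries, with -0.65 ± 0.24 and -1.24 ± 0.21 within the runs (edgeR, Benjamini-Hochberg adjusted p = 0.0287, 0.0345 and 0.00471). The pooled FN1 call was lost without Ad-TGFβ1 replicate 1, 2, 3 or 4 (adjusted p = 0.0657, 0.0737, 0.0724 and 0.0639). The TGFB1 transcript differed by -0.22 ± 0.16, with 6 of 8 libraries below the Ad-TGFβ1 mean (edgeR, Benjamini-Hochberg adjusted p = 0.338). Within the runs it differed by -0.021 ± 0.14 at title numbers 24 and below and by -0.44 ± 0.14 at 25 and above (edgeR, Benjamini-Hochberg adjusted p = 0.903 and 0.0458).

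NR1D1 was at 57.4 ± 6.36 CPM in Ad-TGFβ1 and at 232 ± 199 CPM in Ad-TGFβ1+SR8278, higher than in all Ad-TGFβ1 libraries in 5 of 8 libraries and lower in 3, with no call (1.98 ± 0.81, edgeR, Benjamini-Hochberg adjusted p = 0.0913). It rose by 2.83 ± 0.09 at title numbers 24 and below (edgeR, Benjamini-Hochberg adjusted p = 3.3e-10, all 4 libraries higher) and differed by -0.31 ± 0.35 at 25 and above (adjusted p = 0.549). The pooled call of NR1D1 was gained without Ad-TGFβ1+SR8278 replicate 8 (adjusted p = 0.0385), in 1 fit of all 16 libraries (2.01, adjusted p = 0.0482), with DESeq2 (1.99, adjusted p = 0.0484, a test with 15.4% false calls in the simulated data for this comparison) and with voom (2.16, adjusted p = 0.00201). ARNTL differed by 0.31 ± 0.16, with 6 of 8 libraries above the mean of Ad-TGFβ1 (edgeR, Benjamini-Hochberg adjusted p = 0.179), and by 0.48 ± 0.13 and 0.12 ± 0.14 within the runs (adjusted p = 0.00655 and 0.568). With voom it was called (0.37, adjusted p = 0.0131). NR1D2 differed by 0.18 ± 0.17, with 5 of 8 libraries higher (edgeR, Benjamini-Hochberg adjusted p = 0.488), and by 0.43 ± 0.07 and -0.13 ± 0.13 within the runs (adjusted p = 1.71e-04 and 0.478), and it too was called with voom (0.31, adjusted p = 0.0172). In the clock list 0 genes rose and 3 fell of 21 (2 and 3 adjusted over the list alone), and the median of 0.06 and the mean of 0.27 had the opposite sign to the test (camera, Down, adjusted p = 0.749). Within the runs the list was called in opposite directions, Up with 11 higher and 8 lower at title numbers 24 and below (camera adjusted p = 3.91e-04, and adjusted p = 0.0734 with an estimated correlation) and Down with 0 higher and 4 lower at 25 and above (camera adjusted p = 0.0401, and adjusted p = 0.509 with an estimated correlation). PER1, a repressor within the clock, rose by 2.79 ± 0.09 at title numbers 24 and below and differed by -0.26 at 25 and above (edgeR, Benjamini-Hochberg adjusted p = 3.3e-10 in all 4 libraries and 0.638).

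Of 14919 genes tested, 1765 were higher and 1709 lower in Ad-TGFβ1+SR8278 than in Ad-TGFβ1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 608 and 279 of them by at least 2-fold. Within the runs the counts were 4302 higher and 4442 lower at title numbers 24 and below, and 1537 and 1277 at 25 and above. Without TMM the pooled split became 2875 higher and 806 lower. Leaving out Ad-TGFβ1 replicate 1, 2, 3 or 4 gave 980, 946, 880 and 1072 higher and 973, 919, 850 and 1077 lower genes. Among the called genes, the libraries of the groups did not overlap in 1077 higher and 1162 lower ones. Chance gives no overlap in 0.404% of all genes, called or not. In the genes named next, all 8 libraries lay on the stated side of all 4 Ad-TGFβ1 libraries. The naming rule required this of the largest increases and decreases. Among the largest increases were HIST2H2BE, a histone H2B gene, at 4.04 ± 0.92 (4.89 and 1.79 within the runs) and KLF5, a Krüppel-like transcription factor, at 3.68 ± 0.65 (4.40 and 2.25). Next were CYR61, a matricellular early-response gene, at 3.63 ± 0.81 (4.44 and 1.64) and CXCL2 at 3.33 ± 0.83 (4.15 and 1.29). CHAC1, a glutathione-degrading enzyme gene, was at 3.09 ± 0.61 (3.78 and 1.73) and CLDN1, a tight junction claudin, at 3.03 ± 0.44 (3.46 and 2.43). Among the largest decreases were KLHL41 at -2.83 ± 0.66 (-4.94 and -2.0) and SULF1, a heparan sulfatase gene, at -2.53 ± 0.30 (-2.60 and -2.47). COL8A2 was at -2.10 ± 0.23 (-2.23 and -1.98), KANK4 at -1.81 ± 0.26 (-2.39 and -1.39) and IGF1 at -1.84 ± 0.32 (-2.40 and -1.44). MDFI fell by 1.5 ± 0.21 and ASPN by 1.26. TNFSF15 rose by 2.25 ± 0.47 (1.84 and 2.58) and ALDH1A3 by 2.23 ± 0.46 (2.13 and 2.34).

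**Figure D3:**
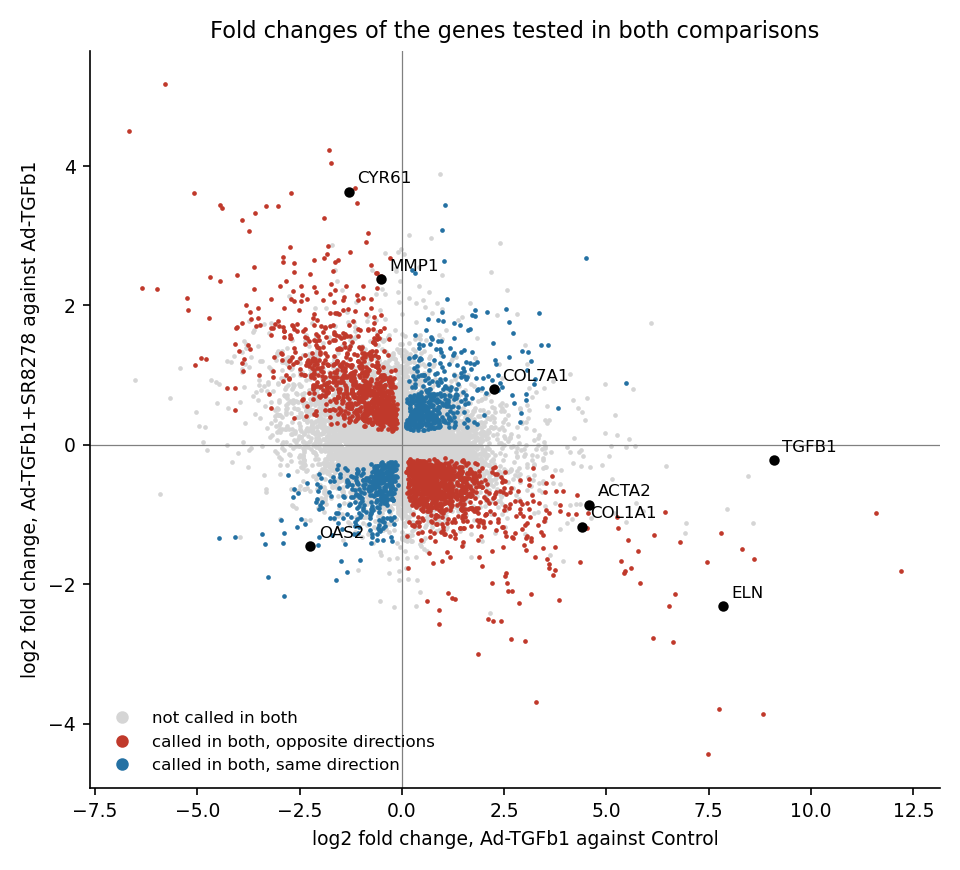
Log2 fold change of each tested gene in Ad-TGFβ1 against Control (x axis) and in Ad-TGFβ1+SR8278 against Ad-TGFβ1 (y axis), sex-linked genes left out, with colours for genes called in both comparisons in the same or in opposite directions. COL1A1 lies at 4.39 and -1.17, ELN at 7.85 and -2.31, and COL7A1 at 2.25 and 0.80.

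The lists of collagens, matrix glycoproteins, collagen processing and proteoglycans were called lower with Ad-TGFβ1+SR8278 at the preset correlation, and that of matrix proteases and inhibitors higher. With an estimated correlation no list was called against Ad-TGFβ1, pooled or within a run, the lowest adjusted p within a run being 0.0549. Of 21 collagens 13 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.59, COL11A1 at -1.37 ± 0.27 and COL1A2 at -1.18 ± 0.23 (camera adjusted p = 2.95e-05, and adjusted p = 0.261 with an estimated correlation). The list medians within the runs were -0.57 and -0.64 (camera adjusted p = 0.0196 and 1.34e-07). COL7A1, the collagen of anchoring fibrils, rose by 0.80 ± 0.11 (0.92 and 0.67 within the runs) and COL12A1, a fibril-associated collagen chosen after its values were seen, by 0.70 ± 0.10 (0.57 and 0.83), both in 8 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 6.92e-04 and 9.3e-04). Of 26 matrix glycoproteins 13 fell and 3 rose (16 and 3 adjusted over the list alone), with COMP at -1.99 ± 0.46, IGFBP3 at -1.64 ± 0.36 and SPARC at -1.0 ± 0.20 (camera adjusted p = 8.19e-06, and adjusted p = 0.261 with an estimated correlation). That list was called lower within the runs too (camera adjusted p = 0.00977 and 5.43e-07). Collagen processing genes fell in 8 of 23 and rose in 1 (10 and 1 adjusted over the list alone), with P4HA2 at -0.80 ± 0.15 (camera adjusted p = 0.00392, and adjusted p = 0.408 with an estimated correlation, 0.0397 and 0.00141 within the runs). Proteoglycans fell in 5 of 16 and rose in 0 (5 and 0 adjusted over the list alone), with FMOD (fibromodulin) at -1.05 ± 0.13 (camera adjusted p = 0.0232, and adjusted p = 0.387 with an estimated correlation). The proteoglycan median of -0.13 became 0.02 without TMM, and the call was absent at title numbers 24 and below (adjusted p = 0.261 and 0.0246 within the runs).

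Contractile genes fell in 5 of 21 and rose in 1 (9 and 2 adjusted over the list alone), with CNN1 at -1.19 ± 0.23 and TAGLN at -1.17 ± 0.25 (camera adjusted p = 0.00392, and adjusted p = 0.426 with an estimated correlation, 0.0327 and 0.00316 within the runs). ACTG2 differed by -0.95, with 8 of 8 libraries below the Ad-TGFβ1 mean, without passing the test (edgeR, Benjamini-Hochberg adjusted p = 0.0824). It passed without Ad-TGFβ1+SR8278 replicate 4 (adjusted p = 0.0325) or 8 (adjusted p = 0.0297), with DESeq2 (-0.94, adjusted p = 0.0475, with the same 15.4% false calls in simulated data), with voom (-1.38, adjusted p = 8.83e-04) and at title numbers 24 and below (-1.43, adjusted p = 0.00391). Smooth muscle and pericyte markers fell in 5 of 11 and rose in 1 (the same counts adjusted over the list alone), with DES at -1.61 ± 0.18 and NOTCH3 at -0.83 ± 0.15 (camera adjusted p = 0.00839, and adjusted p = 0.258 with an estimated correlation, 0.025 and 0.0269 within the runs). IGF1, of the quiescent alveolar fibroblast list, fell from 65.8 to 18.6 CPM after a rise from 1.46 CPM in Control. TCF21 of that list had no pooled call. It was called higher at title numbers 24 and below (0.49, edgeR adjusted p = 4.33e-05) and with voom (0.39, adjusted p = 0.00393). Quiescent alveolar fibroblast genes fell in 9 of 24 and rose in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00542, and adjusted p = 0.258 with an estimated correlation). The call was absent at title numbers 25 and above (adjusted p = 0.00291 and 0.159 within the runs). Interferon-response genes fell in 11 of 39 and rose in 1 (13 and 1 adjusted over the list alone), with OAS2 at -1.45 ± 0.36 (camera adjusted p = 7.59e-04, and adjusted p = 0.223 with an estimated correlation, 0.00977 and 0.00105 within the runs).

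MMP1, interstitial collagenase, went from 128 ± 12.0 to 675 ± 301 CPM, a rise of 2.37 ± 0.36 (2.10 and 2.62 within the runs). MMP3 rose by 2.43 ± 0.42 (1.96 and 2.79) and MMP10 by 2.54 ± 0.31 (2.74 and 2.33), MMP1, MMP3 and MMP10 each being higher in 8 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.00119, 0.00225 and 4.53e-04). MMP11 differed by -0.17 with 6 of 8 libraries below the Ad-TGFβ1 mean (edgeR, Benjamini-Hochberg adjusted p = 0.665), and by -0.71 and 0.23 within the runs (adjusted p = 3.81e-05 and 0.317). It was called lower with voom (-0.53, adjusted p = 0.00489). MMP10, MMP1 and MMP3 are neighbours on chromosome 11, MMP10 from 102770503 to 102780628, MMP1 from 102789920 to 102798160 and MMP3 from 102835801 to 102843803. The list of matrix proteases and inhibitors rose in 8 of 21 and fell in 4 (the same counts adjusted over the list alone, camera adjusted p = 0.00451, and adjusted p = 0.167 with an estimated correlation). That call was absent at title numbers 24 and below (adjusted p = 0.53 and 2.35e-05 within the runs). Inflammatory NF-κB targets rose in 12 of 28 and fell in 1 (16 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 1.48e-05, and adjusted p = 0.258 with an estimated correlation, 1.61e-12 and 0.016 within the runs). Cell cycle genes were higher in 10 of 36 and lower in 9 with no call (camera adjusted p = 0.417), and MKI67 rose by 1.30 ± 0.22 (1.22 and 1.38 within the runs) in 8 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.00232).

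The ATF4, ER stress and cholesterol lists were called higher at the preset correlation, on a part of their genes. ATF4 amino acid genes rose in 10 of 25 and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 9.45e-04, and adjusted p = 0.408 with an estimated correlation). Within the runs 22 of 25 rose at title numbers 24 and below (camera adjusted p = 2.29e-28, and adjusted p = 0.0598 with an estimated correlation) and 4 of 25 at 25 and above (adjusted p = 0.549). PYCR1 of this list went the other way, from 151 CPM in Ad-TGFβ1 to 93.2 CPM in Ad-TGFβ1+SR8278, with 8 of 8 libraries below all Ad-TGFβ1 libraries. ER stress genes rose in 3 of 20 and fell in 0 (the same counts adjusted over the list alone, camera adjusted p = 0.0189, and adjusted p = 0.596 with an estimated correlation). That call was lost without Ad-TGFβ1+SR8278 replicate 5 (adjusted p = 0.0524). Within the runs 17 of 20 rose at title numbers 24 and below (camera adjusted p = 6.3e-10, and adjusted p = 0.118 with an estimated correlation) and 1 of 20 at 25 and above (adjusted p = 0.865). Cholesterol synthesis genes rose in 8 of 24 and fell in 1 (13 and 1 adjusted over the list alone), with HMGCS1 at 1.34 ± 0.26 (1.69 and 0.88 within the runs, camera adjusted p = 4.58e-04, and adjusted p = 0.387 with an estimated correlation, 3.68e-09 and 0.0384 within the runs). Early TGF-β/SMAD response genes had no pooled call (camera adjusted p = 0.222), with 6 of 30 higher and 3 lower (8 and 3 adjusted over the list alone). At title numbers 24 and below 19 were higher and 6 lower (camera adjusted p = 1.24e-04, and adjusted p = 0.379 with an estimated correlation), and at 25 and above 5 and 8 (adjusted p = 0.598). BMP and ID targets, with 3 higher and 2 lower of 15, had no pooled call (camera adjusted p = 0.0786), one gained without Ad-TGFβ1+SR8278 replicate 1 (adjusted p = 0.0495) and at title numbers 25 and above (adjusted p = 0.586 and 0.0273 within the runs, the latter 0.293 with an estimated correlation).

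**Figure D4:**
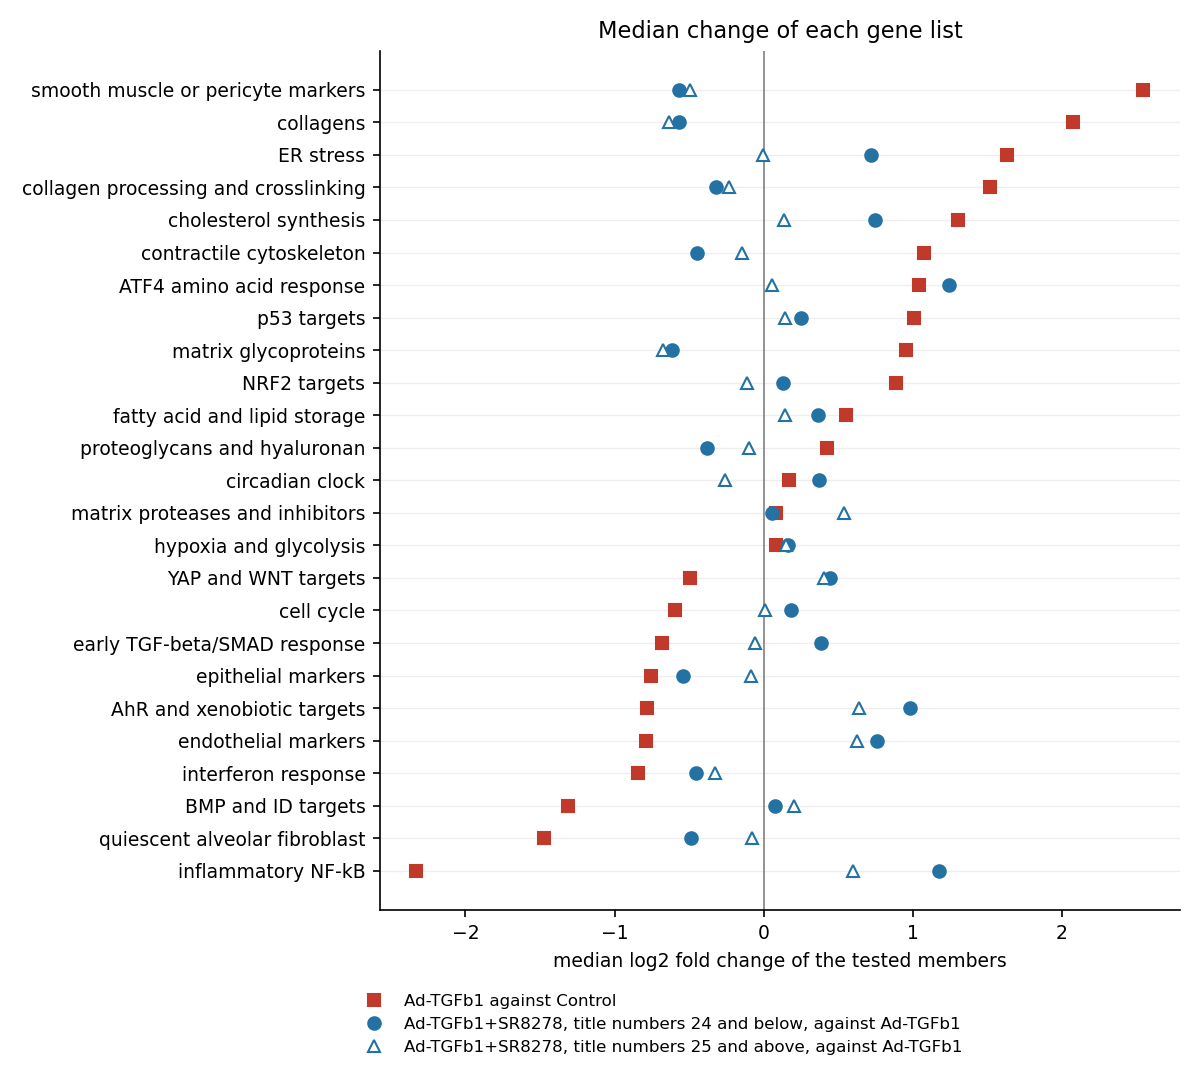
Median log2 fold change of the tested members of each gene list in Ad-TGFβ1 against Control and in the libraries labelled Ad-TGFβ1+SR8278 against Ad-TGFβ1, by run of title numbers. The ATF4 list has medians of 1.04, 1.24 at title numbers 24 and below and 0.06 at 25 and above, and collagens 2.08, -0.57 and -0.64.

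Genes called in both comparisons more often moved in opposite than in equal directions. Of 14453 genes tested in both, 1978 were called in opposite directions, 1048 of them higher in Ad-TGFβ1 than in Control and lower in Ad-TGFβ1+SR8278 than in Ad-TGFβ1, and 930 the reverse, and 804 were called in the same direction. Among the genes tested in both, those are 18.2% of the genes higher and 17.3% of the genes lower in Ad-TGFβ1 than in Control. The comparisons share the Ad-TGFβ1 libraries. Unchanged groups simulated against them 20 times had on average 1.25 and 0.05 called genes, so their overlap of 0 was fixed and is no measure for these counts. Independent lists of the observed sizes would give 678 and 624 opposite and 665 and 636 equal calls. With the Ad-TGFβ1 libraries split between the comparisons, 6 splits gave 53 to 157 opposite and 17 to 67 equal calls. The covariance of the log2 fold changes across genes, which are not independent replicates, was -0.232 against -0.0225 in the simulations, a difference of -0.209. At title numbers 24 and below 3928 calls were opposite and 2996 equal, where independent lists would give 1792 and 1530 opposite and 1678 and 1634 equal, a weaker excess than in the pooled libraries. At 25 and above 1615 were opposite and 722 equal, where independent lists would give 516 and 555 opposite and 607 and 472 equal. These counts too share the Ad-TGFβ1 libraries.

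The comparison of Ad-TGFβ1+SR8278 with Control asks how far the libraries with both labels lay from Control. ACTA2 was higher by 3.72 ± 0.34 (3.59 and 3.84 within the runs), COL1A1 by 3.22 ± 0.26 (2.88 and 3.49) and FN1 by 1.96 ± 0.32 (2.21 and 1.64), each in 8 of 8 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.21e-07, 2.84e-07 and 1.51e-04). TGFB1 was 8.86 ± 0.26 higher (9.04 and 8.64). COL7A1, raised in both steps, was 3.05 ± 0.14 higher than in Control (3.15 and 2.92, edgeR, Benjamini-Hochberg adjusted p = 2.76e-09, 8 of 8 libraries). The GTPase regulator gene RGS16 was higher by 7.84 ± 1.04 (8.59 and 6.01) and the protocadherin gene PCDH1 by 7.18 ± 1.23 (8.02 and 4.81). ARNTL fell by 0.42 ± 0.16, with 7 of 8 libraries below the Control mean (edgeR, Benjamini-Hochberg adjusted p = 0.0391), with -0.26 and -0.61 within the runs (adjusted p = 0.116 and 0.00699). That call was lost without Control replicate 1, 2 or 4 (adjusted p = 0.0585, 0.0697 and 0.155) and without the low-count filter (-0.40, adjusted p = 0.0788). NR1D1 was higher by 2.56 ± 0.84 in 6 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0173), with 3.38 ± 0.10 and 0.27 ± 0.36 within the runs (adjusted p = 2.89e-10 and 0.539). NR1D2 differed by 0.07 ± 0.18, with 5 of 8 libraries higher (edgeR, Benjamini-Hochberg adjusted p = 0.749), by 0.31 and -0.24 within the runs (adjusted p = 0.0019 and 0.146) and by -0.39 without TMM (adjusted p = 0.0210).

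Among the largest decreases from Control were the early growth response gene EGR3 at -6.64 ± 0.27 (-6.28 and -7.17 within the runs), CCL7 at -6.64 ± 0.41 (-6.0 and -7.89) and ADH1B at -6.62 ± 0.40 (-7.60 and -6.03), all in 8 of 8 libraries. TNXB (tenascin X) was at -5.82 ± 0.36 (-6.23 and -5.50), the chemokine gene CXCL12 at -5.40 ± 0.27 (-6.06 and -4.94) and the death ligand gene TNFSF10 (TRAIL) at -5.17 ± 0.33 (-6.08 and -4.60), all in 8 of 8 libraries. The rule that named these largest decreases required no overlap between the groups. In Ad-TGFβ1 against Control, CXCL12 and TNFSF10 were at -4.08 and -3.26. With Ad-TGFβ1+SR8278 they differed further by -1.32 ± 0.26 (-1.97 and -0.86) and -1.90 ± 0.37 (-2.80 and -1.33). Of 15572 genes tested, 4861 were higher and 4711 lower than in Control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 2071 and 2443 of them by at least 2-fold, with 5604 and 5966 at title numbers 24 and below and 4646 and 4528 at 25 and above. Without TMM the split became 2489 higher and 7502 lower. Among the called genes, the libraries of the groups did not overlap in 3534 higher and 3683 lower ones. Chance gives no overlap in 0.404% of all genes, called or not.

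Collagens were higher than in Control in 16 of 21 genes and lower in 2 (camera adjusted p = 1.82e-06, and adjusted p = 0.218 with an estimated correlation). Collagen processing genes were higher in 17 of 23 and lower in 3 (camera adjusted p = 2.83e-09, and adjusted p = 0.127 with an estimated correlation). Contractile genes were higher in 12 of 21 and lower in 2 (camera adjusted p = 0.00293, and adjusted p = 0.554 with an estimated correlation). This call was lost at title numbers 24 and below (adjusted p = 0.229). Matrix glycoproteins were higher in 14 of 26 and lower in 6 (camera adjusted p = 0.0258, and adjusted p = 0.597 with an estimated correlation). Their call was lost without Ad-TGFβ1+SR8278 replicate 5 (adjusted p = 0.0511) and at title numbers 24 and below (adjusted p = 0.229). Proteases and inhibitors were higher in 11 of 21 and lower in 2 (camera adjusted p = 0.00262, and adjusted p = 0.0304 with an estimated correlation). It was lost at title numbers 24 and below (adjusted p = 0.0866). ER stress genes were higher in 19 of 20 and lower in 0 (camera adjusted p = 5.81e-11, and adjusted p = 0.218 with an estimated correlation). ATF4 genes were higher in 22 of 25 and lower in 1 (camera adjusted p = 7.87e-07, and adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes were higher in 19 of 24 and lower in 2 (camera adjusted p = 1.33e-07, and adjusted p = 0.249 with an estimated correlation). Interferon-response genes were lower in 30 of 39 and higher in 1 (camera adjusted p = 1.08e-09, and adjusted p = 0.0274 with an estimated correlation). Quiescent fibroblast genes were lower in 18 of 23 and higher in 2 (camera adjusted p = 1.33e-07, and adjusted p = 0.0494 with an estimated correlation). Cell cycle genes were lower in 23 of 36 and higher in 1 (camera adjusted p = 6.98e-04, and adjusted p = 0.0274 with an estimated correlation). BMP and ID targets were lower in 9 of 15 and higher in 3 (camera adjusted p = 4.33e-04, and adjusted p = 0.0274 with an estimated correlation). Inflammatory targets were lower in 19 of 31 and higher in 2 (camera adjusted p = 1.9e-05, and adjusted p = 0.249 with an estimated correlation). Counts adjusted over the list alone equalled those of this comparison in these lists. Clock genes, early TGF-β/SMAD genes, proteoglycans and smooth muscle markers had no pooled call (camera adjusted p = 0.433, 0.359, 0.96 and 0.119). Within the runs the clock list was called higher at title numbers 24 and below (camera adjusted p = 0.00453), the early TGF-β/SMAD list there too (adjusted p = 0.0404) and smooth muscle markers at 25 and above (adjusted p = 0.0303). With an estimated correlation these were not called (adjusted p = 0.112, 0.600 and 0.307).

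The planned check of homogeneity compared title numbers 25 and above with 24 and below within the label Ad-TGFβ1+SR8278. Libraries also varied within each run, FN1 ranging from 22583 to 60151 CPM and ELN from 209.8 to 945 CPM at 24 and below, and from 22335 to 47797 CPM and from 221 to 1083 CPM at 25 and above. In order of title number at 25 and above, TGFB1 was at 84964, 75757, 64160 and 52630.5 CPM. NR1D1 was there at 88.9, 46.0, 32.2 and 20.7 CPM and ELN at 1083, 444, 290 and 221 CPM. In that order ACTA2 was at 1499, 1429, 927 and 354 CPM at 24 and below, but at 1476, 1054, 1140 and 1236 CPM at 25 and above. The tests take the libraries of a run as replicates without order, and a trend with title number was not tested. DDIT3, which encodes the stress transcription factor CHOP, fell by 4.16 ± 0.49, from 698 ± 32.1 to 38.3 ± 33.3 CPM, HSPA5 by 1.98 ± 0.26, from 16967 ± 546 to 4206 ± 1895 CPM, and NR1D1 by 3.12 ± 0.37, from 416 ± 28.4 to 46.9 ± 29.8 CPM, each in 4 of 4 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.6e-04, 4.65e-04 and 2.61e-04). PER1 fell by 3.03 ± 0.40, CYR61 by 2.79 and HIST2H2BE by 3.07, and PLAT rose by 1.11, all in 4 of 4 libraries. Against Ad-TGFβ1, DDIT3 and HSPA5 rose by 4.37 ± 0.10 and 2.11 ± 0.09 at title numbers 24 and below, and differed by 0.19 ± 0.45 and 0.12 ± 0.24 at 25 and above (edgeR, Benjamini-Hochberg adjusted p = 3.05e-11, 3.94e-09, 0.781 and 0.756). The libraries at 25 and above lay on both sides of Ad-TGFβ1. In order of title number DDIT3 was there at 87.3, 30.5, 19.8 and 15.6 CPM, against 28.8 to 39.2 CPM in Ad-TGFβ1. HSPA5 was at 6864, 4196, 3199 and 2565 CPM, against 3494 to 4122 CPM. ARNTL differed by -0.35 ± 0.17 with 4 of 4 libraries below the mean of the other run (edgeR, Benjamini-Hochberg adjusted p = 0.144). COL1A1 was 0.61 ± 0.19 higher at 25 and above in 4 of 4 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0312), a call lost without Ad-TGFβ1+SR8278 replicate 3, 5, 6 or 7 (adjusted p = 0.0862, 0.0591, 0.0541 and 0.0562).

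Of 14485 genes tested between the runs, 2452 were higher and 2216 lower at title numbers 25 and above (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 823 and 627 of them by at least 2-fold. ATF4 genes were lower in 17 of 25 and higher in 0 (18 and 0 adjusted over the list alone, camera adjusted p = 6.19e-12, and adjusted p = 0.168 with an estimated correlation). ER stress genes were lower in 17 of 20 and higher in 0 (the same counts adjusted over the list alone, camera adjusted p = 1.35e-09, and adjusted p = 0.329 with an estimated correlation). Clock genes were lower in 10 of 21 and higher in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 1.06e-05, and adjusted p = 0.329 with an estimated correlation). Collagens were higher in 5 and lower in 0 (2 and 0 adjusted over the list alone), and contractile genes higher in 3 and lower in 1 (3 and 0 adjusted over the list alone), neither list being called (camera adjusted p = 0.389 and 0.207). All 13 mitochondrially encoded messenger RNAs were higher at 25 and above, with a median of 2.62, and both mitochondrial ribosomal RNAs lower, with a median of -1.22. The mitochondrial share of counts was 4.35% ± 0.664 at 25 and above and 2.21% ± 0.208 at 24 and below, a difference of 2.14 percentage points (exact two-sided permutation test, p = 0.0286, the smallest it can give, adjusted p = 0.0571). Across the runs, 2066 genes were called in the same direction against Ad-TGFβ1 and 156 in opposite directions, where independent lists would give 438 and 401 in the same direction and 373 and 470 in opposite directions. The runs share the Ad-TGFβ1 libraries, and simulated unchanged groups had too few calls, 0.80 and 0.15 on average, for their overlap of 0 to be a measure. With the Ad-TGFβ1 libraries split between the runs, 6 splits gave 31 to 95 in the same direction and 0 to 1 in opposite directions, and the covariance was 0.201 against 0.0205 in the simulations, a difference of 0.180.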

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

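The tests of a wrong label, of something the label does not name, of a few genes taking most counts, of the TGFB1 level and of the scaling were chosen after the result was seen. In 12 of 246 groups of values 1 library stood apart from the rest of its group, and chance gives about 1 in 20. On the log2(CPM + 1) scale, Ad-TGFβ1+SR8278 replicate 4 was lowest of its label in ACTA2 (8.47, the others 9.86 to 10.55), TAGLN (8.91, the others 9.88 to 10.71) and CNN1 (4.02, the others 4.99 to 5.66). Ad-TGFβ1+SR8278 replicate 8 was highest in PAPPA-AS1 (4.26, the others 0) and TNFSF15 (3.63, the others 1.68 to 2.6), and replicate 3 in CCL7 (0.82, the others 0 to 0.34). In Ad-TGFβ1, replicate 4 was lowest in CDKN1A (10.83) and highest in IGFBP3 (11.02), replicate 3 was lowest in HERC6 (1.01) and highest in KLF5 (1.82), and replicate 1 was highest in ALDH1A3 (1.32). In Control, replicate 1 was highest in ADAM19 (3.49).

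The 8 libraries labelled Ad-TGFβ1+SR8278 fell into separate sets by title number, with 4668 genes called between them (edgeR). After every library was thinned to the smallest total 4502 genes were still called, which argues against library size. Title numbers 25 and above called 2814 genes against Ad-TGFβ1, and the highest of the other splits among 35 of those 8 libraries called 1, so these sets of libraries differ. That does not settle a wrong label, since Ad-TGFβ1 libraries of another batch could call genes too. That 1 run was given something its label does not name may be an explanation, and it stays open. The other labels each fill a single block of title numbers, while this label holds both runs. The series title also names STL1267, which no label carries. ARNTL, which REV-ERB proteins repress, differed by -0.35 ± 0.17 (edgeR, Benjamini-Hochberg adjusted p = 0.144), and doses and times are not given. Other clock genes did differ between the runs. NR1D2 was at -0.55 (edgeR, Benjamini-Hochberg adjusted p = 0.0152), a call lost without Ad-TGFβ1+SR8278 replicate 2 or 7. NR1D1 averaged 416 CPM at 24 and below and 46.9 CPM at 25 and above, and PER1 530 and 63.4 CPM. A batch of culture or sequencing that follows the title numbers cannot be told apart from an unnamed treatment by these genes. No biological explanation was tested because the labels give both runs the same group.

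Mitochondrial messenger and ribosomal RNAs moved apart at title numbers 24 and below. The mean log2 ratio of ribosomal to messenger counts was 0.387 ± 0.382 there, -2.38 ± 0.0670 in Ad-TGFβ1, -2.44 ± 0.0992 in Control and -2.34 ± 0.226 at title numbers 25 and above (SD). The difference of 2.77 from Ad-TGFβ1, with no overlap of libraries, argues against a few genes taking most of the counts, which would move both classes alike. Weaker poly(A) selection could raise ribosomal RNAs and stays open. Of 68 transcripts searched that were taken to lack a poly(A) tail, HIST2H2BE being left out, 25 were tested. They had a median of -0.46 with a bootstrap error of 0.280, 0 being higher and 8 lower at 25 and above. The median lay within its error of the cut-off set for the test, so the test cannot decide. HIST2H2BE averaged 58.0 CPM at 24 and below and 6.67 CPM at 25 and above, so including it would lower the median. Among the tested transcripts RN7SK was at -3.24, and RN7SL1 and RN7SL2 at -0.07 and 0.09. Against Ad-TGFβ1, all 13 mitochondrial messenger RNAs were called lower at title numbers 24 and below, with a median of -2.25. The test of transcripts without a tail does not address that fall. No biological explanation was tested, the runs having 1 label.

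COL1A1 was lower in the libraries labelled Ad-TGFβ1+SR8278 than in Ad-TGFβ1. At title numbers 24 and below TGFB1 differed by -0.021 ± 0.14 while COL1A1 was called lower, which argues against less TGFB1 transcript as the cause there. At 25 and above TGFB1 differed by -0.44 ± 0.14, so a lower TGFB1 level could contribute and stays open. Without TMM COL1A1 differed by -1.03 and was still called, which argues against the scaling. The labelled compound, as a biological explanation, remains a hypothesis beside the open ones.

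Other splits of the same libraries were counted by edgeR calls, to ask whether the real grouping calls more genes than they do. For Ad-TGFβ1 against Control, 1 of 35 splits, the real one, gave as many as 11630 genes, and the highest other gave 0. For Ad-TGFβ1+SR8278 against Ad-TGFβ1, 1 of 100 splits drawn from 495 gave 3474, the highest other of those drawn giving 171. For Ad-TGFβ1+SR8278 against Control it was 1 of 100, with 9572 and 55, and for the runs of title numbers 1 of 35, with 4668 and 20. In each comparison the real split called more genes than the other splits counted so far. Splits that mix the groups call few genes when many genes differ, and the libraries may be technical repeats. The counts therefore show that these groups of libraries differ, but they cannot exclude chance between cultures or donors. A split of the 12 libraries that was not among those drawn follows the title numbers, 24 and below against the other 8. It gave 5910 genes, more than the real 3474. The within-run counts against Ad-TGFβ1 were 8744 and 2814. The corresponding split with Control gave 5579.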

How the results depend on the processing

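The tests with library totals without TMM and with the TGFB1 gene removed were chosen after the result was seen. The split of calls moved most without TMM: 2528 higher and 9910 lower in Ad-TGFβ1 against Control, 2875 and 806 in Ad-TGFβ1+SR8278 against Ad-TGFβ1, and 2489 and 7502 in Ad-TGFβ1+SR8278 against Control. The higher group then made up 20.3%, 78.1% and 24.9% of calls, against 49.4%, 50.8% and 50.8% with TMM. In Ad-TGFβ1+SR8278 against Ad-TGFβ1, voom with sample weights called 3990 and 4361, and title numbers 24 and below alone 4302 and 4442. Leaving out each library in turn gave 880 to 2222 higher and 850 to 2298 lower genes there, the counts falling to 980 and 973, 946 and 919, 880 and 850, and 1072 and 1077 without Ad-TGFβ1 replicates 1, 2, 3 and 4. Fewer Ad-TGFβ1 libraries leave less information on the spread. Leave-one-out ranges elsewhere were 5563 to 5737 higher and 5744 to 5914 lower in Ad-TGFβ1 against Control, 4382 to 4964 and 4229 to 5104 in Ad-TGFβ1+SR8278 against Control, and 3256 to 6421 between the runs of title numbers. Under RLE factors, DESeq2, no low-count filter, the stricter filter, 1 fit of all 16 libraries and removal of mitochondrial genes or of TGFB1, the counts of these 3 comparisons stayed within 1.5 times those with TMM. They ran from 4615 to 6072 higher and 4694 to 6522 lower in Ad-TGFβ1 against Control, 1301 to 2539 and 1450 to 2065 in Ad-TGFβ1+SR8278 against Ad-TGFβ1, and 4343 to 5337 and 4468 to 5131 in Ad-TGFβ1+SR8278 against Control. Genes called in opposite directions numbered 1599 to 2420 in these settings and without TMM, 3988 with voom, 3928 at title numbers 24 and below, and 981 to 2659 when a library was left out (1128, 1096, 981 and 1241 without Ad-TGFβ1 replicates 1 to 4). Camera with a fixed correlation called 17 lists in Ad-TGFβ1 against Control, 18 in Ad-TGFβ1+SR8278 against Ad-TGFβ1 and 16 in Ad-TGFβ1+SR8278 against Control. With an estimated correlation it called 5, 0 and 6, and fry called 25, 19 and 20. Reversed values were NR1D1 in Ad-TGFβ1 against Control without TMM (-0.012), NR1D2 in Ad-TGFβ1+SR8278 against Control without TMM (-0.39), and, at title numbers 24 and below, PLAT against Ad-TGFβ1 (-0.60) and CXCL2 against Control (0.55). Of the named genes' values, 12 lost and 5 gained their call in 1 fit of all 16 libraries, 1 and 9 with DESeq2, and 9 and 10 without TMM. The counts were 12 and 6 at title numbers 25 and above, 1 and 15 at 24 and below, 0 and 13 with voom, 1 and 2 without the low-count filter, 1 and 0 with RLE factors, and 0 and 1 with the stricter filter. Without mitochondrial genes or without TGFB1 they were 0 and 0. The cause of these changes was not tested. As to depth, 4502 genes were called between the runs with every library thinned to the smallest total, against 4668. Recovery of simulated changes was not split by depth or level.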

Other observations

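The tests of list medians without TMM here were chosen after the result was seen, and CTGF, which the rule does not take, was named after its values were seen. Of 21 p53 targets 18 rose and 1 fell in Ad-TGFβ1 against Control, with CDKN1A, the cell cycle inhibitor p21, at 2.65 ± 0.06 in 4 of 4 libraries (camera adjusted p = 6.51e-06, and adjusted p = 0.054 with an estimated correlation). Of 22 NRF2 targets 17 rose and 3 fell, with HMOX1, heme oxygenase 1, at 2.08 ± 0.06 (camera adjusted p = 2.66e-05, and adjusted p = 0.143 with an estimated correlation). Fatty acid genes had no call there (12 of 25 higher, 8 lower, camera adjusted p = 0.0896), with a median of 0.55 that became -0.02 without TMM. With Ad-TGFβ1+SR8278 against Ad-TGFβ1, fatty acid genes rose in 7 of 25 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.258 with an estimated correlation, 0.0115 and 0.0253 within the runs). PDK4, a brake on glucose oxidation, rose by 2.05 ± 0.29 (2.22 and 1.87 within the runs) in 8 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 9.71e-04). The p53 targets rose in 5 of 21 and fell in 1 (the same counts adjusted over the list alone, camera adjusted p = 0.0204, and adjusted p = 0.258 with an estimated correlation, 0.0115 and 0.0337 within the runs). NRF2 targets rose in 5 of 22 and fell in 1 (the same counts adjusted over the list alone), with no call (camera adjusted p = 0.279). Against Control, Ad-TGFβ1+SR8278 was higher in 19 p53 targets and lower in 0 (camera adjusted p = 6.52e-07, and adjusted p = 0.0274 with an estimated correlation). It was higher in 18 NRF2 targets and lower in 1 (18 and 2 adjusted over the list alone, camera adjusted p = 1.45e-05, and adjusted p = 0.107 with an estimated correlation), and in the fatty acid list higher in 13 fatty acid genes and lower in 2 (camera adjusted p = 4.12e-04, and adjusted p = 0.127 with an estimated correlation).

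AhR and xenobiotic genes fell in 9 of 11 and rose in 2 in Ad-TGFβ1 against Control (camera adjusted p = 0.0396, and adjusted p = 0.133 with an estimated correlation), a call lost without Control replicate 1 (adjusted p = 0.0607) or Ad-TGFβ1 replicate 2 (adjusted p = 0.0550). They rose in 6 of 11 and fell in 0 with Ad-TGFβ1+SR8278 against Ad-TGFβ1 (the same counts adjusted over the list alone, camera adjusted p = 7.59e-04, and adjusted p = 0.223 with an estimated correlation, 7.83e-06 and 0.00155 within the runs). ALDH1A3 was at 2.23 and the drug efflux pump ABCG2 at 1.87 ± 0.36 (1.47 and 2.20), each in 8 of 8 libraries. YAP and WNT targets were lower in 12 of 21 and higher in 5 in Ad-TGFβ1 against Control with no call (camera adjusted p = 0.0511). A call was gained without Control replicate 1, 3 or 4 or Ad-TGFβ1 replicate 1 (adjusted p = 0.0259, 0.0124, 0.0436 and 0.0452). They rose in 9 of 22 and fell in 1 with Ad-TGFβ1+SR8278 against Ad-TGFβ1 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00734, and adjusted p = 0.223 with an estimated correlation, 0.0108 and 6.12e-04 within the runs). The matricellular gene CTGF differed by -0.76 ± 0.08 in Ad-TGFβ1 against Control (edgeR, Benjamini-Hochberg adjusted p = 9.95e-07, 4 of 4 libraries lower), a call lost in 1 fit of all 16 libraries (-0.76, adjusted p = 0.281). It was 2.57 ± 0.65 higher in Ad-TGFβ1+SR8278 than in Ad-TGFβ1 in 8 of 8 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0138), with 3.31 and 1.01 within the runs. That call was lost without Ad-TGFβ1 replicate 3 (2.52, adjusted p = 0.0501). Against Control neither list was called (camera adjusted p = 0.96 for AhR genes and 0.423 for YAP and WNT targets), and their means of 0.33 and 0.05 differed in sign from their medians of -0.24 and -0.06 and from the test.

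Hypoxia genes had no call in Ad-TGFβ1 against Control (13 of 27 higher and 9 lower, 13 and 10 adjusted over the list alone, camera adjusted p = 0.889). They had none in Ad-TGFβ1+SR8278 against Ad-TGFβ1 (10 of 28 higher and 3 lower, 11 and 4 adjusted over the list alone, camera adjusted p = 0.153, though 0.00265, and adjusted p = 0.139 with an estimated correlation, at title numbers 24 and below) or against Control (camera adjusted p = 0.305). Markers of epithelial, endothelial, immune and mesothelial cells had no call in Ad-TGFβ1 against Control (camera adjusted p = 0.631, 0.117, 0.483 and 0.631) or in Ad-TGFβ1+SR8278 against Control (camera adjusted p = 0.433, 0.977, 0.996 and 0.871). In Ad-TGFβ1+SR8278 against Ad-TGFβ1, endothelial markers rose in 3 of 7 and fell in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0232, and adjusted p = 0.258 with an estimated correlation), a call absent within each run (adjusted p = 0.239 and 0.291). Epithelial and immune markers had no call there (camera adjusted p = 0.608 and 0.241), and mesothelial markers had too few tested members. Between the runs, early TGF-β/SMAD genes were lower at title numbers 25 and above in 14 of 30 and higher in 2 (15 and 3 adjusted over the list alone), and inflammatory targets in 13 of 28 and higher in 0 (14 and 1). Cholesterol genes were lower in 15 of 24 and higher in 1 (16 and 1) and hypoxia genes in 8 of 27 and higher in 4 (8 and 5). Quiescent fibroblast genes were higher in 11 of 22 and lower in 2 (12 and 2). For these lists in this order the camera adjusted p-values were 5.03e-08, 2.46e-08, 2.18e-07, 0.0144 and 0.00367, and adjusted p = 0.256, 0.168, 0.329, 0.329 and 0.168 with an estimated correlation.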
